A study of Homo sapiens with 12 samples.

How the data were processed

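Gene expression was measured by RNA sequencing in 12 libraries, 2 per group, from 2 human AML cell lines. MOLM13 cells carried the control hairpin shNS, hairpin 1 (shBP3-1) or hairpin 2 (shBP3-2) against IGF2BP3, delivered by lentivirus. U937 cells with mAID-tagged IGF2BP3 were untreated (NT) or held in 5-Ph-IAA for 6 h or 24 h. Total RNA is named as the molecule for MOLM13 and polyadenylated RNA for U937, whereas a protocol text given for all libraries describes capture of mRNA on beads, so the kind of library was examined from the values themselves.

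Per the submitters' processing notes, reads were trimmed with cutadapt 4.1, aligned to hg38 with HISAT2 2.1.1, counted per gene with HTSeq 2.0.2 and compared with DESeq2. The signal value in the deposited tables is, per the file headers, the DESeq2 base mean, a read count divided by each library's size factor by the authors and averaged over the 4 libraries of a comparison. The log2 values are the fold changes of the treated group over its control as the authors deposited them. The p-value in the deposited tables is the one the authors adjusted over genes, and genes without one had been left untested by the authors. The form of the authors' test, any shrinkage of the fold changes and the release of the gene annotation are not stated. No values per library were held, so values per library, their spread and an SD are not given.

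The planned edgeR or limma fits need values per library, so the case provided for tables without them was used: the authors' DESeq2 statistics as deposited. A gene counted as changed at an adjusted p under 0.05 with no minimum fold. Unadjusted p-values were recovered by undoing the Benjamini-Hochberg step, and a standard error was computed from each p and fold change on the assumption of a normal (Wald) test. The 95% intervals rest on that assumption and cannot be given where an adjusted p is listed as 0. Group means were worked out from base mean and fold change. Size factors and depth were read from the lowest repeated mean counts, which come from 2 reads in a single library of the comparison. Control depths worked out separately from both tables of a line differed by at most 0.23% (shNS) and 0.125% (NT). Genes with a mean count of at least 1000 had an implied spread between replicates of 6.97% (hairpin 1), 5.66% (hairpin 2), 4.32% (6 h) and 3.48% (24 h). Reads are not independent molecules, so counting error is a lower limit. The lowest mean count of a tested gene was 10.4 with hairpin 1, 2.46 with hairpin 2, 16.4 at 6 h and 6.52 at 24 h, so the tables tested different numbers of genes.

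There were 4 comparisons with a control, and results were compared between hairpins, between times and between cell lines over genes tested in each. Because both comparisons of a line share 2 control libraries, overlaps and correlations are given beside the overlap of independent lists and beside 100 simulations of unchanged groups with shared controls. The overlap between cell lines was tested with Fisher's exact test. The planned direct fits of hairpin 2 against hairpin 1 and of 24 h against 6 h could not be made. In their place the difference of the deposited log2 fold changes was divided by the root of the summed squared standard errors and adjusted by Benjamini-Hochberg, a test added after the tables were seen. It treats the shared controls as separate, which makes the standard error too large, and 12 genes of each pair had no usable standard error.

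The gene lists (28), the rule for named genes, the threshold and most alternatives were fixed before the data were examined. The lists came from general knowledge of the field and cover the groups named in the results. Some genes are in several lists, so results of different lists are not independent. For each list with at least 5 tested members the median log2 fold change was compared with 10000 random lists matched on mean expression in 20 bins, two-sided, and adjusted over the lists of a comparison by Benjamini-Hochberg. The smallest p these random lists can give is 0.0002 before adjustment. Intervals of list medians are bootstrap intervals over members (10000 draws). The test describes how a list stands among genes: correlation between genes could not be estimated without values per library. As an alternative, limma's cameraPR was run on signed z values with an inter-gene correlation set to 0.01. Named genes were the IGF2BP family, the 8 highest and 8 lowest log2 fold changes among changed genes with a symbol and a mean count of at least 50, up to 4 members per list with the largest change, the 6 largest shared changes per direction, and 4 per direction for differences. Not every gene that the rule gives is reported here. The part of the rule asking that libraries of the groups do not overlap could not be applied. A few further genes (MYC, ATF4, HOXA9, HOXA10, MEIS1, CDK6, BCL2, CTSD and others quoted as list members) were chosen after their values were seen.

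Coordinates and gene types came from GENCODE 29, matched by identifier without version. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1. Recovery of standard errors, the list test and the difference test were tested on simulated data. With simulated changes, 52.9% (hairpin 1), 61.8% (hairpin 2), 41.2% (6 h) and 70.6% (24 h) of genes changed by 0.5 on the log2 scale were called in the right direction, and 80.3%, 83.3%, 87.9% and 95.5% of those changed by 1. Of the genes called in these simulations, 2.53%, 5.23%, 6.79% and 5.85% were unchanged genes. Few genes were changed in the simulations, so calls met a stricter cutoff than in the deposited data. The shares of changed genes called may therefore understate detection there. Alternatives were a stricter adjusted p of 0.01, a minimum absolute log2 fold change of 1, a minimum mean count of 50, fold changes centred on the median gene, and cameraPR. No library was left out.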

Results

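RNA sequencing was used to ask how gene expression changes in human acute myeloid leukemia (AML) cells when the RNA-binding protein IGF2BP3 is lost. The 12 libraries came from 2 AML cell lines and fell into 6 groups of 2 libraries. MOLM13, a line with monocytic features that carries a KMT2A fusion, received lentivirus with a control hairpin (shNS) or with one of 2 hairpins against IGF2BP3, called hairpin 1 and hairpin 2 here. U937, a monocytic line, carried IGF2BP3 fused to a mini-auxin-inducible degron (mAID). This tag lets the auxin analogue 5-Ph-IAA trigger degradation of the fused protein. The U937 cells were untreated or received the analogue for 6 h or 24 h. The labels describe the MOLM13 material as total RNA and the U937 material as polyadenylated RNA.

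The deposited tables compare one treated group with its control and hold, per gene, the mean normalised read count over both groups, a log2 fold change and an adjusted p. No value per library was held, so depth was read from the smallest mean counts, which are made of 2 reads. Worked out in this approximate way, MOLM13 libraries held 21853081 to 23429971 reads in listed genes and U937 libraries 10214912 to 15176967, and which replicate had which depth is not known. For genes with a mean count of at least 1000, the standard error implied by the adjusted p had a median of 0.11 (hairpin 1), 0.09 (hairpin 2), 0.07 (6 h) and 0.06 (24 h) on the log2 scale. Nothing states that the 2 replicates of a group were separate cultures, so the p-values may measure technical spread alone. A gene is said to have risen or fallen where the authors' deposited table gives it an adjusted p under 0.05.

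The level of IGF2BP3 itself (ENSG00000136231.14, chromosome 7, 23310209 to 23470467, minus strand, hg38) served as a check of the labels of the knockdown. In the authors' deposited table its mRNA was at 40.0% of the control with hairpin 1 (log2 fold change -1.32, 95% interval -1.55 to -1.10, adjusted p = 2.3e-28). With hairpin 2 the authors' deposited table puts it at 48.8% of the control (-1.03, -1.22 to -0.85, adjusted p = 1.6e-26). The difference between the hairpins in this fall (0.29 on the log2 scale, SE 0.15 from the authors' DESeq2 statistics) did not pass its test (adjusted p = 0.15). In the degron line the protein and not the mRNA is the target. Protein levels were not examined here, so its loss in U937 is taken from the labels. There the authors' deposited tables give the IGF2BP3 mRNA a log2 fold change of -0.27 at 6 h (adjusted p = 0.17) and 0.15 at 24 h (adjusted p = 0.25). Of the paralogs, IGF2BP1 fell with hairpin 1 (-0.62) and hairpin 2 (-0.28) in the authors' deposited tables, and it was not listed in the U937 tables. IGF2BP2 fell with hairpin 1 (-0.24, adjusted p = 0.039), at 6 h (-0.85) and at 24 h (-0.67), and stood at 0.03 with hairpin 2 (adjusted p = 0.82), by the authors' deposited tables.

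Hairpin 1 against shNS asked what follows in MOLM13 when IGF2BP3 is knocked down. Interferon-stimulated genes rose furthest and cell cycle, histone, ribosomal protein, and glutamine and one-carbon genes fell. In the authors' deposited table, 5492 of 16282 tested genes passed the threshold, 2886 up and 2606 down, and 837 rose and 569 fell at least 2-fold. Among genes with a mean count of at least 50, the highest log2 fold changes in the authors' deposited table were those of IFI27 (9.62, 95% interval 8.18 to 11.07), IFI44L (255-fold), the sialic acid receptor SIGLEC1 (7.12) and IFI6 (6.27). IFIT1 (5.99), OAS2 (5.89), EPSTI1 (5.74) and OAS3 (5.72) followed in the authors' deposited table. The control level of IFI27 worked out at 2.02 normalised reads, so the size of its fold is loosely determined. With the same minimum, the lowest log2 fold changes in the authors' deposited table belonged to the matrix protein gene MFAP4 (-3.80, -4.20 to -3.39), HOXB9 (-3.29), LOXHD1 (-3.17), the glycine transporter SLC6A9 (-3.15), the glutathione-degrading enzyme CHAC1 (-3.13), STC2 (-2.96), asparagine synthetase ASNS (-2.88) and PCDHGC5 (-2.78).

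By gene list, all 31 tested members of the type I interferon response rose with hairpin 1 (31 adjusted over the list alone). Their median log2 fold change was 2.79 (95% bootstrap interval 1.76 to 3.81, adjusted permutation p = 0.00037 against random lists). Of the antigen presentation genes 14 of 19 rose and none fell (14 adjusted over the list alone, median 1.19), among them the class II transactivator CIITA (2.03) and the peptide transporter TAP1 (1.81) in the authors' deposited table. Lysosome and autophagy genes rose in 24 of 27 cases and fell in 1 (24 and 1 adjusted over the list alone, median 0.73), with the protease genes CTSL (3.28) and CTSD (1.55) in the authors' deposited table. Of 28 myeloid differentiation genes 17 rose and 3 fell (17 and 4 adjusted over the list alone). They included lysozyme LYZ (2.55) and, falling, FCER1G (-2.08) in the authors' deposited table. Primary granule genes rose in 9 of 13 cases and fell in 1 (9 and 1 adjusted over the list alone, median 0.68), the exception being myeloperoxidase MPO (-1.50 in the authors' deposited table). NF-kB genes rose in 11 of 17 cases (median 0.65) and immediate early genes in 15 of 24 with 4 falling (median 0.71), the latter with EGR2 at 2.29 in the authors' deposited table. Adjusted over the list alone, 11 and 16 rose.

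Among the lists that fell with hairpin 1, the G1/S and DNA replication genes did so in 28 of 29 cases (28 adjusted over the list alone, median -1.07) and the G2/M genes in 26 of 28 (26 adjusted over the list alone, median -0.96). The helicase subunit MCM2 (-1.41), the replication factor CDC45 (-1.47) and the proliferation marker MKI67 (-1.40) are examples from the authors' deposited table. Replication-dependent histone genes fell in 18 of 19 cases (19 adjusted over the list alone, median -1.58), such as H2BC14 (-2.23) and H3C2 (-1.85) in the authors' deposited table. All 55 ribosomal protein genes fell (55 adjusted over the list alone, median -0.63). Of 30 MYC and ribosome biogenesis genes 20 fell and none rose (23 adjusted over the list alone, median -0.42), with MYC itself at -0.98 in the authors' deposited table. Glutamine and one-carbon genes fell in 13 of 19 cases and rose in 3 (13 and 3 adjusted over the list alone, median -0.63), led in the authors' deposited table by ASNS, the serine synthesis enzymes PSAT1 (-2.53) and PHGDH (-2.05), and GPT2 (-1.81). Of the ATF4 and unfolded protein response genes 15 fell and 7 rose among 28 (the same counts adjusted over the list alone). The HOXA and MEIS1 programme fell in 8 of 18 cases and rose in 1 (8 and 1 adjusted over the list alone, median -0.33), and the anti-apoptotic gene BCL2 fell by 1.74 in the authors' deposited table. The adjusted permutation p against random lists was 0.00037 for each of these lists by its median (-0.48 for the ATF4 list), except 0.025 for the HOXA and MEIS1 programme. The 95% bootstrap interval of the ATF4 list's median reached from -1.21 to 0.07. Mitochondrially encoded genes had a median of -0.68 with 5 of 13 members called (5 adjusted over the list alone), a shift that the cameraPR test did not call (adjusted p = 0.097).

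Hairpin 2 against shNS asked the same question with another target sequence. Cell cycle, histone, HOXA and cholesterol genes fell, and myeloid differentiation, lysosome and interferon genes rose. In the authors' deposited table, 8616 of 20768 tested genes passed the threshold, 4019 up and 4597 down (4409 and 4146 once centred on the median gene), with 1847 up and 1613 down at least 2-fold. The IgA receptor gene FCAR (6.43, 95% interval 5.18 to 7.68), the homeobox gene MEIS3 (5.47), CRISPLD2 (5.29) and the chemokine CXCL8 (5.15) had the highest log2 fold changes in the authors' deposited table at a mean count of at least 50, ahead of AHNAK2 (4.95), MAB21L3 (4.84), IFI6 (4.71) and ACP5 (4.57). The lowest in the authors' deposited table, at the same minimum, were HOXB9 (-5.88, -7.17 to -4.59), the fatty acid desaturase FADS2 (-5.53), the telomerase gene TERT (-4.07), SLC6A9 (-3.98) and the mitotic kinase PBK (-3.89). LINC01229 (-3.80), LGALS12 (-3.68) and PCDHGC5 (-3.61) came next in the authors' deposited table. HOXB9 with hairpin 2 worked out at 3.01 normalised reads, so its fold is loosely determined.

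All 29 G1/S genes fell with hairpin 2 (29 adjusted over the list alone, median -2.47, 95% bootstrap interval -2.67 to -2.21), and 27 of 28 G2/M genes did (27 adjusted over the list alone, median -2.63, -2.75 to -2.59). MCM10 (-3.25), CDC45 (-3.11), AURKB (-3.22) and the cyclin-dependent kinase CDK1 (-3.04) are examples from the authors' deposited table. Histone genes fell in 19 of 20 cases (19 adjusted over the list alone, median -2.23) and ribosome biogenesis genes in 29 of 30 (30 adjusted over the list alone, median -1.15). The HOXA and MEIS1 programme fell in 14 of 19 cases (15 with 1 rise adjusted over the list alone, median -1.01), with HOXA10 at -2.30 and the receptor FLT3 at -1.69 in the authors' deposited table. Cholesterol genes fell in 21 of 27 cases and rose in 2 (21 and 2 adjusted over the list alone, median -0.73), and glutamine and one-carbon genes fell in 16 of 19 and rose in 2 (16 and 2 adjusted over the list alone, median -0.80). Stearoyl-CoA desaturase SCD (-2.94), PSAT1 (-3.18), PHGDH (-3.04) and the glutamine transporter SLC1A5 (-2.31) are examples from the authors' deposited table. Of 32 myeloid differentiation genes 25 rose and 1 fell (26 and 1 adjusted over the list alone, median 1.30), with LYZ (3.30), the oxidase subunit CYBB (3.28) and VCAN (2.95) in the authors' deposited table. Primary granule genes rose in 10 of 13 cases and fell in 2 (10 and 2 adjusted over the list alone, median 1.06). Lysosome genes rose in 26 of 27 cases and fell in 1 (26 and 1 adjusted over the list alone, median 1.36), led by GPNMB (3.78) and CTSD (3.57) in the authors' deposited table. ATF4 and unfolded protein response genes went both ways, with 15 falls and 9 rises among 29 (the same adjusted over the list alone, median -0.72, 95% bootstrap interval -1.58 to 0.17). Interferon genes rose in 23 of 31 cases (24 adjusted over the list alone, median 1.19), and p53 targets in 14 of 23 with 5 falling (14 and 5 adjusted over the list alone, median 0.76). For each list of this paragraph the adjusted permutation p against random lists was 0.0008 or lower, except 0.0011 for the glutamine and one-carbon genes. Ribosomal protein genes fell in 35 of 55 cases and rose in 2 (37 and 2 adjusted over the list alone), but their median of -0.25 did not stand apart from that of random lists (adjusted permutation p = 0.25), although cameraPR called the list lower (adjusted p = 7.7e-05).

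**Figure D1:**
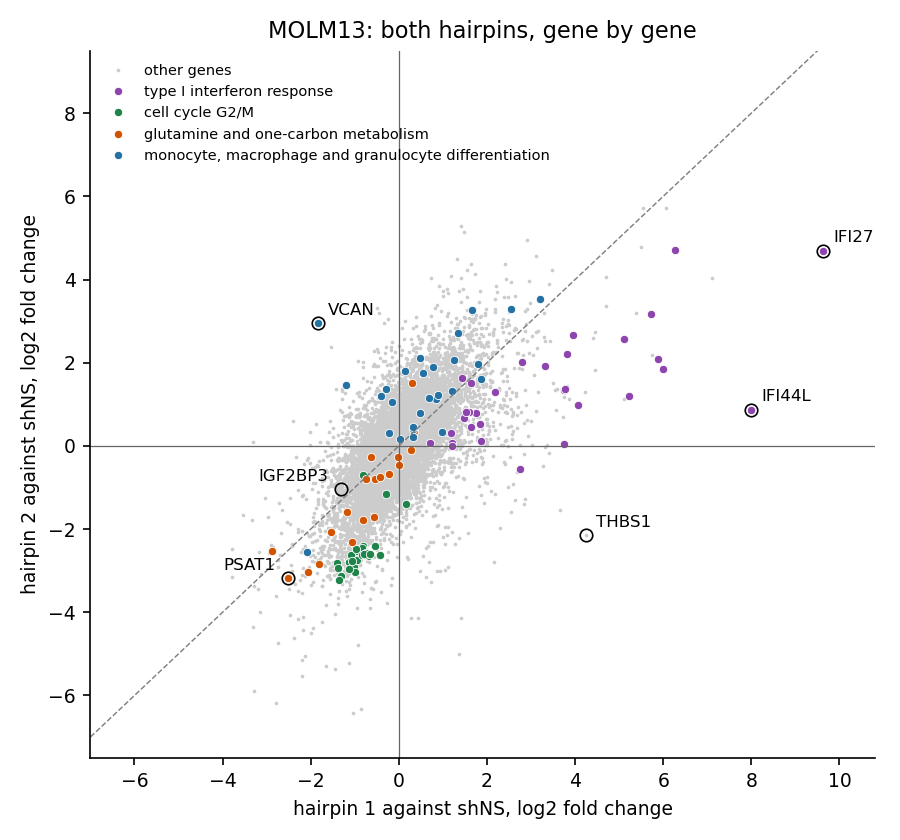
Log2 fold change of each gene tested in both MOLM13 tables, hairpin 1 on the horizontal and hairpin 2 on the vertical axis, with members of 4 gene lists in colour and 6 genes named; the dashed line marks equal change. Most interferon genes lie below the line on the side of hairpin 1 (27 of 31 lower with hairpin 2), and G2/M genes lie below it with larger falls with hairpin 2.

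Both hairpins together, 3917 genes passed the threshold in the same direction among 16268 tested in both tables, 1848 up and 2069 down, and 290 in opposite directions. Independent lists of those sizes would share 658.6 and 730.4. By mean log2 fold change in the authors' deposited tables, among genes with a mean count of at least 50, IFI27 (7.16), SIGLEC1 (5.57), IFI6 (5.49), OAS3 (4.44), LGALS3BP (4.03) and OAS2 (3.99) led the shared rises. HOXB9 (-4.59), FADS2 (-3.86), SLC6A9 (-3.57), TERT (-3.27), PCDHGC5 (-3.20) and MFAP4 (-3.14) led the shared falls by the same measure and minimum. The minimum did not hold for each hairpin by itself. IFI27 missed it with hairpin 2 (log2 fold change 4.69), so its mean is loosely determined. Across genes, which are not independent replicates, the log2 fold changes correlated with r = 0.65 and rho = 0.64. Unchanged groups simulated against the same 2 controls gave a mean r of 0.43 and 0 shared calls. With every simulated gene unchanged, the adjusted p lets almost no call through, so the 0 is no baseline for the shared count. The covariance was 0.46, against 0.065 in the simulation, a difference of 0.40. The 2 controls could not be split further, so part of the excess may come from the shared controls.

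Where the hairpins differed was tested on the difference of their log2 fold changes, which come from tables normalised separately. Of 16256 genes, 1485 lay higher and 2970 lower with hairpin 2 at an adjusted p under 0.05. Interferon genes lay lower with hairpin 2 in 27 of 31 cases (median difference -1.39, 95% bootstrap interval -2.41 to -1.14). G2/M genes did so in 27 of 28 cases (-1.75, -1.83 to -1.60) and G1/S genes in all 29 (-1.45, -1.50 to -1.22). Ribosome biogenesis genes lay lower in 28 of 30 cases (-0.80), cholesterol genes in 20 of 27 with 1 higher (-0.86), and the HOXA and MEIS1 programme in 12 of 18 with 1 higher (-0.60). Higher with hairpin 2 were 12 of 28 myeloid differentiation genes (0.51, 1 lower), 14 of 27 lysosome genes (0.37, 1 lower) and 35 of 55 ribosomal protein genes (0.36, 1 lower).

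Degradation of IGF2BP3 for 6 h in U937 asked which transcripts change early. Cholesterol, ATF4-linked, and glutamine and one-carbon genes fell. In the authors' deposited table, 3236 of 13940 tested genes passed the threshold, 1515 up and 1721 down, of which 77 and 186 changed at least 2-fold. Among genes with a mean count of at least 50, INSIG1, which holds back sterol synthesis, fell furthest (log2 fold change -3.63, 8.06% of the control left) in the authors' deposited table. The stress gene SESN2 (-2.86), the sterol enzyme MSMO1 (-2.73) and the mTOR inhibitor DDIT4 (-2.29) also fell in the authors' deposited table, as did C6orf223 (-2.54), SCIRT (-2.45) and OLMALINC (-2.38). The oxysterol receptor GPR183 (2.86, 95% interval 2.32 to 3.40), TREM1 (2.66), TNFRSF14 (2.50), the autophagy gene TP53INP2 (2.16) and heme oxygenase HMOX1 (1.89) rose furthest in the authors' deposited table, with ATP2B2 (1.89), SH3PXD2A (1.86) and MVP (1.74).

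Cholesterol genes fell at 6 h in 22 of 26 cases (23 adjusted over the list alone, median -1.32, 95% bootstrap interval -1.61 to -0.89), among them SCD (-2.06) and HMGCS1 (-1.95) in the authors' deposited table. ATF4 and unfolded protein response genes fell in 23 of 28 cases and rose in 1 (24 and 1 adjusted over the list alone, median -0.95), with ATF4 itself at -1.10 in the authors' deposited table. Glutamine and one-carbon genes fell in 16 of 19 cases (18 adjusted over the list alone, median -0.64), such as PSAT1 (-2.07), GPT2 (-1.48) and the cystine transporter SLC7A11 (-1.82) in the authors' deposited table. Each of these 3 lists had an adjusted permutation p of 0.0016, and glycolysis and hypoxia genes, 16 of 29 down and 2 up (the same adjusted over the list alone, median -0.26), had 0.0036. Primary granule genes fell in 6 of 12 cases (6 adjusted over the list alone), with MS4A3 at -1.70 and proteinase 3 (PRTN3) at -0.81 in the authors' deposited table. G2/M genes fell in 12 of 27 cases (12 adjusted over the list alone, median -0.16, adjusted permutation p = 0.044). G1/S genes were mixed, 12 up and 5 down among 29 (13 and 6 adjusted over the list alone). Their median of 0.14 passed the random-list test (adjusted permutation p = 0.034) but not cameraPR (adjusted p = 0.24). Interferon genes showed 0 rises and 3 falls among 24 (0 and 2 adjusted over the list alone, median 0.09), and the myeloid differentiation list 6 rises and 4 falls among 20 (7 and 5 adjusted over the list alone). Neither median stood apart from random lists (adjusted permutation p = 0.40 and 0.23).

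After 24 h of degradation the falls of the cholesterol, ATF4-linked and one-carbon genes were still present, G1/S genes had fallen, and some G2/M and HOXA genes had risen. In the authors' deposited table, 6250 of 16104 tested genes passed the threshold, 3051 up and 3199 down, with 360 and 514 changing at least 2-fold. Among genes with a mean count of at least 50, NBPF17P had the lowest log2 fold change (-6.47) in the authors' deposited table; it is a pseudogene in a family of near-identical copies, which makes its count uncertain. The signalling inhibitor SPRY4 (-4.02, 95% interval -4.88 to -3.16), PSAT1 (-3.90, 6.71% of the control left), INSIG1 (-3.35), NLRP12 (-2.84), ADM2 (-2.79), NCF1C (-2.68) and MSMO1 (-2.62) followed in the authors' deposited table. The transcription factor JUN (2.66, 2.51 to 2.82), the opioid precursor PDYN (2.53), MVP (2.42), CREB5 (2.29) and TASL (2.20) rose furthest in the authors' deposited table, ahead of NUDT16L1 (2.16), the lipid droplet protein PLIN2 (4.30-fold) and PATL2 (1.96). NCF1C is also a pseudogene, and its parent NCF1 stood at -2.78 in the authors' deposited table.

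G1/S genes fell in 27 of 29 cases at 24 h and rose in 1 (28 and 1 adjusted over the list alone, median -0.94, 95% bootstrap interval -1.12 to -0.81), such as CDC6 (-1.74), E2F1 (-1.50) and PCNA (-1.42) in the authors' deposited table. G2/M genes rose in 15 of 28 cases and fell in 4 (15 and 5 adjusted over the list alone, median 0.20, adjusted permutation p = 0.041), with the mitotic kinase PLK1 at 1.33 and CDC20 at 1.04 in the authors' deposited table. Cholesterol genes fell in 23 of 26 cases (23 adjusted over the list alone, median -1.33), ATF4 and unfolded protein response genes fell in 24 of 28 and rose in 2 (24 and 2 adjusted over the list alone, median -1.21), and glutamine and one-carbon genes fell in 18 of 19 and rose in 1 (18 and 1 adjusted over the list alone, median -1.09). SCD (-2.37), FADS2 (-2.06), SLC7A11 (-2.24) and PHGDH (-1.77) are examples from the authors' deposited table. Mitochondrially encoded genes fell in 12 of 14 cases (12 adjusted over the list alone, median -0.63), MT-ND1 by 0.77 in the authors' deposited table. The HOXA and MEIS1 programme rose in 10 of 18 cases and fell in 2 (11 and 2 adjusted over the list alone, median 0.56), with HOXA9 at 1.17 and MEIS1 at 0.65 but BCL2 at -0.98 in the authors' deposited table. All of these lists except the G2/M list had an adjusted permutation p of 0.00077. Of 21 myeloid differentiation genes 10 rose and 4 fell (10 and 4 adjusted over the list alone, median 0.31, adjusted permutation p = 0.037): LYZ rose (1.06), and NCF1, ITGAM (-1.75) and S100A9 (-1.70) fell in the authors' deposited table. Interferon genes went both ways, 7 up and 4 down among 26 (7 and 4 adjusted over the list alone, median 0.15, adjusted permutation p = 0.32). Lysosome and autophagy genes, which rose with both hairpins, had 5 rises and 13 falls among 26 at 24 h (6 and 13 adjusted over the list alone). Their median of -0.15 did not stand apart from random lists (adjusted permutation p = 0.30).

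The 2 times shared 1850 genes changed in the same direction among 13938 tested in both U937 tables, 754 up and 1096 down, and 402 changed in opposite directions. Independent lists would share 323.9 and 391.2. GPR183 (2.23), MVP (2.08), TP53INP2 (2.03), JUN (1.76), PSCA (1.58) and SYT11 (1.53) led the shared rises by mean log2 fold change in the authors' deposited tables, among genes with a mean count of at least 50. NBPF17P (-4.37), INSIG1 (-3.49), PSAT1 (-2.98), SPRY4 (-2.81), MSMO1 (-2.68) and SESN2 (-2.60) led the shared falls by the same measure and minimum. Across genes r was 0.50 and rho 0.44, against a mean r of 0.41 and 0 shared calls in simulations with unchanged groups and the same controls. For the reason given for the hairpins, the 0 is no baseline for the shared count. The covariance was 0.11, against 0.027 in the simulation, a difference of 0.085. The 2 NT libraries could not be split either. Between the times, 1522 of 13926 genes lay higher and 1703 lower at 24 h by the test of the difference, across tables normalised separately. G1/S genes lay lower at 24 h in 25 of 29 cases (median difference -1.08, 95% bootstrap interval -1.29 to -0.75), and G2/M genes higher in 17 of 27 with 1 lower (0.46, 0.19 to 0.65). The HOXA and MEIS1 programme lay higher in 9 of 16 cases (0.46) and mitochondrially encoded genes lower in 10 of 13 (-0.44). Cholesterol genes differed little as a list (0.03, -0.28 to 0.28), with 5 higher and 6 lower.

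**Figure D2:**
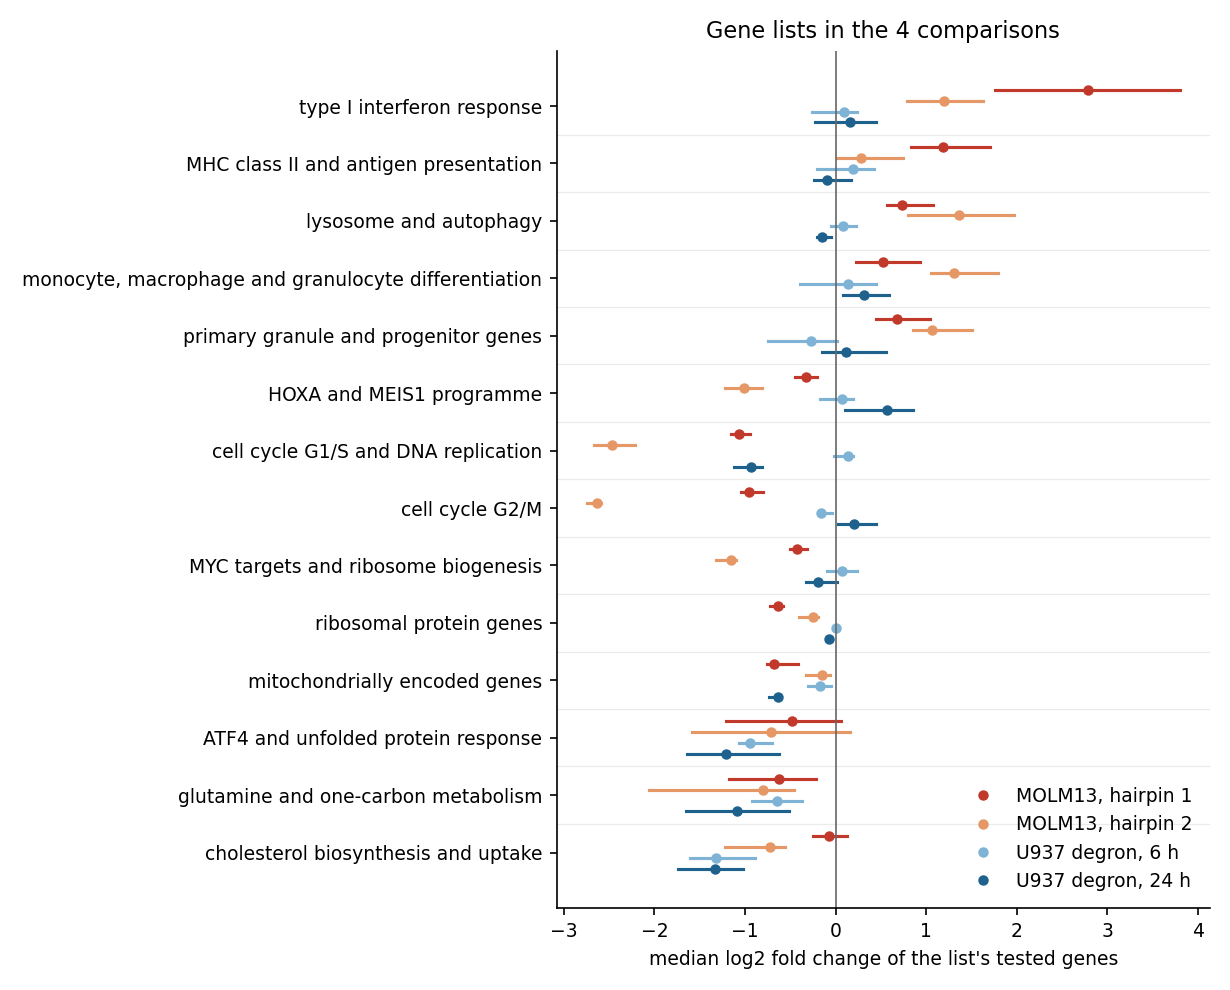
Median log2 fold change of 14 gene lists (points) with 95% bootstrap intervals over the tested members (lines), for both hairpins in MOLM13 and both times in U937. One-carbon genes lie below 0 in each comparison, whereas G2/M genes lie at -2.63 with hairpin 2 and at 0.20 after 24 h.

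Across the cell lines the question was which changes accompany IGF2BP3 loss in both systems. PSAT1, FADS2, GPT2, SLC1A5 and BCL2 fell, and GPR183, TP53INP2 and JUN rose, in all 4 comparisons. Among 11693 genes tested in all 4 tables, 502 rose and 867 fell with both hairpins and at 24 h, where independent lists would share 373.5 and 444.4. Fisher's exact test gave odds ratios of 1.61 (p = 2.0e-15) and 3.60 (p = 5.9e-124), two-sided, over genes that are not independent. At 6 h the shared numbers were 292 up (194.6 for independent lists) and 428 down (246.0), with odds ratios of 1.77 (p = 2.5e-14) and 2.33 (p = 4.8e-37) by the same exact test. Of the genes that changed with both hairpins, 319 that rose and 301 that fell went the opposite way at 24 h, where independent lists would give 390.7 and 424.8. At 6 h the opposite changes numbered 234 and 244, against 216.3 and 221.3 for independent lists. Independent lists and the exact test take no account of mean count, which affects how easily a gene is called in each table. The mean hairpin log2 fold change correlated across genes with that at 24 h (r = 0.22, rho = 0.20) and at 6 h (r = 0.12, rho = 0.085). In the authors' deposited tables OASL (3.07), OAS1 (2.51), TP53INP2 (2.37), GPR183 (2.34), LYZ (2.31) and SLFN5 (2.27) had the highest mean over both hairpins and 24 h among genes called in all of them with a mean count of at least 50. FADS2 (-3.26), PSAT1 (-3.20), INHBE (-2.83), TERT (-2.70), ST6GALNAC3 (-2.68) and ASNS (-2.55) had the lowest by the same measure and minimum. All 4 comparisons shared 160 rises and 324 falls.

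**Figure D3:**
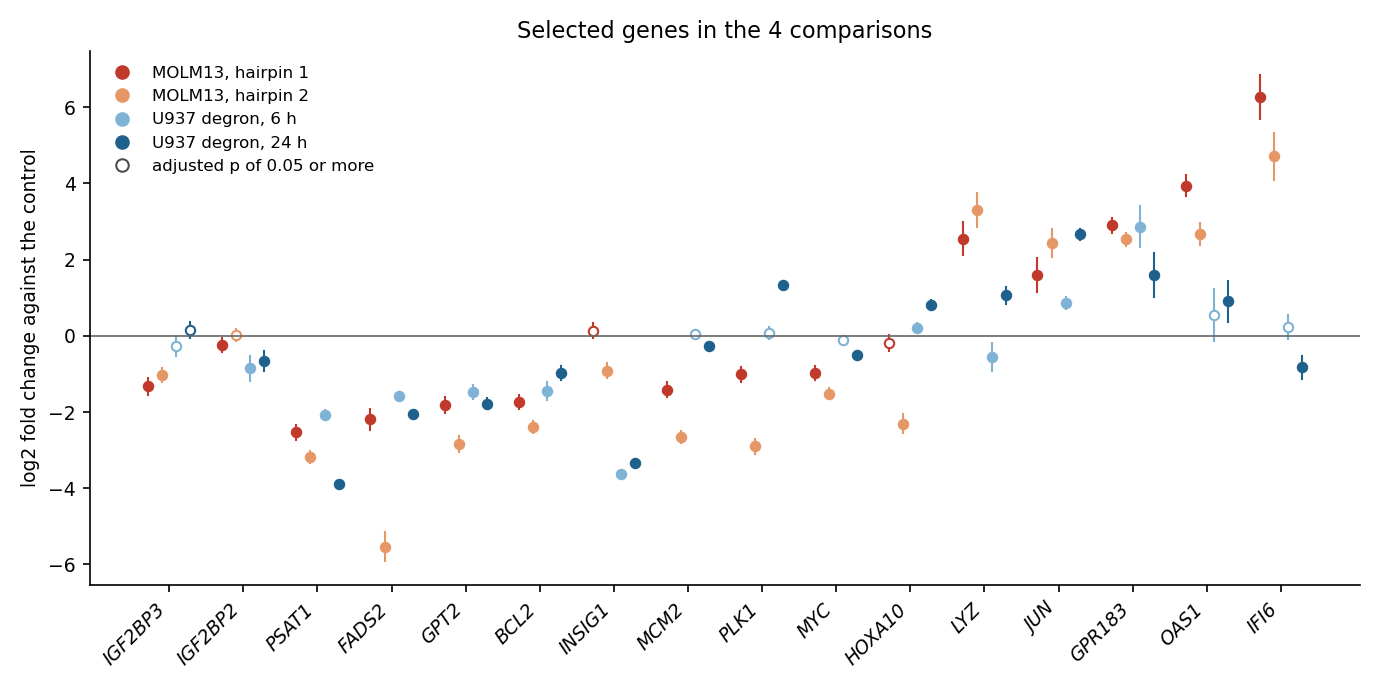
Log2 fold change against the control of 16 genes in the 4 comparisons, with the 95% interval implied by the deposited adjusted p; open points did not pass the threshold, and points whose adjusted p is listed as 0 have no interval. PSAT1, FADS2, GPT2 and BCL2 lie below 0 in each comparison, and IGF2BP3 passed the threshold with both hairpins and at neither time.

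Transcripts described elsewhere as bound or stabilised by IGF2BP proteins, among them genes of growth and glutamine use, formed a further list. It shares members with other lists, so its changes partly repeat theirs. GPT2 and SLC1A5 are also glutamine and one-carbon genes, and BCL2 is also in the HOXA and MEIS1 programme. With hairpin 1, 13 of its 20 tested members fell and 6 rose (13 and 7 adjusted over the list alone, median -0.43, 95% bootstrap interval -0.77 to 0.25). With hairpin 2, 15 fell and 3 rose (15 and 4 adjusted over the list alone, median -1.11). Of 19 members tested in U937, 10 fell and 3 rose at 6 h (11 and 3 adjusted over the list alone, median -0.31, interval -0.54 to 0.01), and 12 fell and 5 rose at 24 h (13 and 5 adjusted over the list alone, median -0.65). The adjusted permutation p was 0.0018, 0.00043, 0.0067 and 0.00077 in that order. GPT2 (-1.81, -2.84, -1.48 and -1.78), SLC1A5 (-1.07, -2.31, -0.56 and -1.15) and BCL2 (-1.74, -2.40, -1.44 and -0.98) fell throughout in the authors' deposited tables. MYC fell with both hairpins (-0.98 and -1.52) and at 24 h (-0.49) and stood at -0.11 at 6 h (adjusted p = 0.09) in the authors' deposited tables. HOXA9 fell with the hairpins (-0.36 and -1.14) and rose at 24 h (1.17), and CDK6 fell with hairpin 1 (-0.23), stood at 0.15 with hairpin 2 (adjusted p = 0.064) and rose at 24 h (0.97), by the authors' deposited tables. The leukemia stem cell score genes had 1 rise and 3 falls among 9 tested with hairpin 1, 3 and 5 among 11 with hairpin 2, 0 and 0 among 7 at 6 h, and 1 and 2 among 7 at 24 h. Adjusted over the list alone these were 2 and 4, 4 and 6, 0 and 0, and 1 and 3. Only the median with hairpin 2 (-0.79) passed the random-list test (adjusted permutation p = 0.013), and cameraPR did not call it (adjusted p = 0.12); DNMT3B fell with both hairpins (-1.95 and -1.84) in the authors' deposited tables.

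The remaining lists moved less uniformly. Glycolysis and hypoxia genes fell in 15 of 30 cases and rose in 2 at 24 h (16 and 3 adjusted over the list alone). Their median of -0.35 passed the random-list test (adjusted permutation p = 0.0018) and cameraPR (adjusted p = 1.6e-06). Apoptosis regulators rose in 13 of 25 cases and fell in 5 with hairpin 1 (13 and 5 adjusted over the list alone, median 0.39, adjusted permutation p = 0.0023), BIRC3 rising (2.91) and HRK falling (-1.94) in the authors' deposited table. With hairpin 2 they had 13 rises and 6 falls (13 and 6 adjusted over the list alone, median 0.37), and at 6 h 8 rises and 4 falls among 23 (8 and 5 adjusted over the list alone, median 0.23 but mean -0.01). The last 2 shifts passed the random-list test (adjusted permutation p = 0.013 and 0.018) and not cameraPR (adjusted p = 0.30 and 0.80), nor did immediate early genes with hairpin 2 (10 up and 5 down among 25, the same adjusted over the list alone, adjusted p = 0.16). Aryl hydrocarbon receptor targets rose in 7 of 11 cases and fell in 1 with hairpin 1 (8 and 1 adjusted over the list alone, median 0.93) and rose in 7 of 12 and fell in 1 with hairpin 2 (the same adjusted over the list alone, median 0.83). p53 targets had 7 rises and 5 falls among 23 with hairpin 1 (8 and 5 adjusted over the list alone, adjusted permutation p = 0.083). At 24 h p53 targets had 3 rises and 8 falls among 20 (4 and 9 adjusted over the list alone, median -0.42), a shift with adjusted permutation p = 0.0013 that cameraPR did not call (adjusted p = 0.094). The m6A writers, erasers and readers fell in 12 of 18 cases and rose in 1 with hairpin 2 (the same adjusted over the list alone, adjusted permutation p = 0.19, cameraPR adjusted p = 0.011) and rose in 11 of 18 and fell in 2 at 24 h (11 and 3 adjusted over the list alone, median 0.27, adjusted permutation p = 0.037). NF-kB genes rose in 10 of 21 cases and fell in 2 with hairpin 2 (12 and 2 adjusted over the list alone, median 0.78), with CXCL8 and IL1A (2.93) in the authors' deposited table. Antigen presentation genes rose in 8 of 20 cases and fell in 1 with hairpin 2 (the same adjusted over the list alone, adjusted permutation p = 0.20, cameraPR adjusted p = 0.047). Further lists called by cameraPR and not by random lists were cholesterol genes with hairpin 1 (lower, adjusted p = 0.028), mitochondrially encoded genes at 6 h (lower, adjusted p = 3.4e-11), and at 24 h primary granule genes (higher, adjusted p = 0.029), ribosome biogenesis genes (lower, adjusted p = 0.0011) and erythroid and megakaryocyte markers (lower, adjusted p = 0.022). Several of these were mixed. Cholesterol genes had 3 rises and 8 falls among 27, and mitochondrially encoded genes 0 and 8 among 13. At 24 h primary granule genes had 4 rises and 3 falls among 12, and ribosome biogenesis genes 5 and 15 among 30. The erythroid and megakaryocyte markers had 0 rises and 1 fall among 5, with a median of -0.30 but a mean of 0.48. Markers of other cell types were few: lymphoid markers had 3 rises and 2 falls among 5 with hairpin 1 and 1 and 2 among 9 with hairpin 2, erythroid and megakaryocyte markers 0 and 0 among 3 and 0 and 2 among 4, and stromal, epithelial and packaging cell markers 2 and 0 among 5 and 0 and 1 among 6. Adjusted over the list alone the stromal list had 3 rises with hairpin 1, and the counts of the other marker lists were the same.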

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

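The tests of differences between hairpins and between times, and every test of an explanation in the paragraphs on interferon genes and on one-carbon genes, were chosen only after the results were seen. The tests of the histone pattern were fixed before theirs. The gene list tests that the paragraphs on interferon and one-carbon genes draw on were planned.

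A difference between hairpins, tested on the log2 fold changes themselves, was found for 4455 genes, and a difference between times for 3225. The widest named differences are given as hairpin 2 minus hairpin 1. IFI44L (-7.12), THBS1 (-6.38), SLAMF7 (-5.20) and IFI27 (-4.93) were lower with hairpin 2, and VCAN (4.79), CRISPLD2 (3.88), GPR141 (3.82) and CXCL8 (3.67) were higher. The difference of IFI27 is loosely determined (SE 1.15), because its control level was low. THBS1 rose by 4.24 with hairpin 1 and fell by 2.14 with hairpin 2 in the authors' deposited tables, SLAMF7 stood at 3.67 and -1.53, and VCAN at -1.84 and 2.95. As 24 h minus 6 h, NBPF17P (-4.22), TNFRSF14 (-2.95), TREM1 (-2.52) and FAM222A (-2.44) were lower at 24 h. CREB5 (2.82), UNC5C (2.77), TASL (2.64) and PDYN (2.46) were higher at 24 h. UNC5C stood at -1.53 at 6 h and 1.24 at 24 h in the authors' deposited tables. NBPF17P belongs to a family of near-identical copies, and reads shared between copies were not tested as a source of its change. With 2 libraries per group and no values per library, no search for libraries far from their group was possible.

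Interferon genes rose with both hairpins, further with hairpin 1, and not as a list in the degron cells. An effect of IGF2BP3 loss that reaches the same size in both lines by 24 h is argued against, since the list's median at 24 h (0.15) and its interval lay below the interval with hairpin 2. Of 26 members tested in both, 15 lay lower at 24 h and 0 higher. This holds only if the protein was lost in U937, which was not measured here. The depth of the knockdown as the reason for the order of the hairpins cannot be told apart from other differences between them: IGF2BP3 stood lower with hairpin 1 (hairpin 2 minus hairpin 1, 0.29), but this difference did not pass its test (adjusted p = 0.15). An innate response to a hairpin or its vector, to a degree that differs between constructs, may explain the rise. It cannot be told apart from a slow effect of IGF2BP3 loss in MOLM13, because the list also rose with hairpin 2 (median 1.19) and cell line and method change together.

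Glutamine and one-carbon genes fell in all 4 comparisons, and ATF4-linked genes had medians below 0 in each, although their intervals reached past 0 with both hairpins. The lists share members, among them ASNS, PSAT1 and PHGDH, and are not independent. A fall of G1/S mRNAs as the upstream event in U937 is argued against by the order in time, since the G1/S list stood at 0.14 at 6 h when the ATF4 list had already fallen. Entry into S phase itself was not measured. Some G2/M genes stood lower at 6 h (12 down and 0 up among 27, median -0.16). At 24 h the G2/M list had 15 rises and 4 falls among 28 (median 0.20), so this early fall did not last. An effect of IGF2BP3 loss on the one-carbon and ATF4-linked genes may be a candidate explanation and stays a hypothesis. An effect of 5-Ph-IAA itself in U937, on these genes or on cholesterol genes, stays open and was not tested, because untagged cells given the drug were not analysed here.

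Histone mRNAs were abundant in the MOLM13 tables and scarce in the U937 tables (median ratio 386, 95% bootstrap interval 166 to 730). Libraries that kept RNAs without a poly(A) tail in MOLM13 may explain this, because other such RNAs had a median ratio of 188 (11.8 to 707), above 1 for 12 of 13. In these ratios RNAs not listed in the U937 tables, among them 8 of the 13, were set to 2 reads over the 4 libraries of a table, the lowest total listed. More cycling cells in MOLM13 as the source of so large a ratio are argued against, since G1/S genes had a ratio of 0.43. These levels average control and treated libraries. G1/S genes fell with both hairpins (medians -1.07 and -2.47) and at 24 h (-0.94), so 0.43 is not a ratio of untreated cells. The levels come from tables normalised separately and were not tested across them, nor was the biology of the lines as a further reason.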

How the results depend on the processing

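The centring on the median gene, cameraPR and all settings of the difference tests were chosen after the data were seen. Counts stayed within 1.5 times the reported value, and the calls for IGF2BP3 were the same, in 30 alternatives. The other 9 were those that asked for an absolute change of at least 1 on the log2 scale, whose construction removes smaller changes. With that minimum 1406 genes were left for hairpin 1, 3460 for hairpin 2, 263 at 6 h and 874 at 24 h. Shared changes came to 900 for both hairpins, 131 for both times and 107 for both hairpins with 24 h. Differences of at least 1 numbered 1257 between hairpins and 394 between times.

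An adjusted p under 0.01 gave 4211, 7233, 2339 and 4951 genes for the 4 comparisons in the same order. A mean count of at least 50 gave 5352, 7973, 3292 and 6155, and centring gave 5495, 8555, 3241 and 6247. With hairpin 2 centring turned the larger side from falls (4597 against 4019 rises) to rises (4409 against 4146 falls). Centring moved the split of the differences between hairpins from 1485 higher and 2970 lower to 1881 and 2367, because the median difference of all genes was -0.10. Removing variance shared through the controls raised the differences to 6153 and 4681. Of 103 list tests, 59 passed with random lists, 55 with the higher mean count and 60 with cameraPR, and 52 passed by both kinds of test.

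Not run for want of values per library were refits with DESeq2 or edgeR, scaling by library size alone, no filter on low counts, a fit over all 3 groups, other pseudocounts, leaving out each library, camera with an estimated correlation, fry, and the direct fits of hairpin 2 against hairpin 1 and 24 h against 6 h. No paired analysis was possible because no values per library were held. In simulated tables changes of 0.5 were found least often at 6 h (41.2%) and most often at 24 h (70.6%). Few genes were changed in these simulations, so calls met a stricter cutoff than in the deposited data. The shares are therefore no measure of detection in the deposited data.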

Other observations

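Families of genes that were not planned as lists were examined after the gene tables were seen. Some of their members are also in the lists. The kinesin gene KIF20A is in the G2/M list, and the HNRNP gene HNRNPA2B1 is among the m6A writers, erasers and readers. Results of these families are therefore not independent of those of the lists. Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs and include ATF4 targets, fell in 11 of 17 cases and rose in 1 with hairpin 1 (median log2 fold change -0.51), and 16 of 17 fell with hairpin 2 (-0.92). They fell in 12 of 17 cases and rose in 1 at 6 h (-0.34), and fell in 13 and rose in 2 at 24 h (-0.53). The adjusted permutation p against random lists was 0.0020, 0.00050, 0.012 and 0.0020 in that order. Splicing factors of the SRSF and HNRNP families fell in 23 of 39 cases and rose in 1 with hairpin 1 (-0.30) and fell in 31 of 44 with hairpin 2 (-0.69). Host genes of small nucleolar RNAs fell in 10 of 21 and 15 of 24 cases (-0.50 and -0.82), and initiation factor subunits in 20 of 60 and 41 of 70 (-0.18 and -0.47, with 4 and 3 rises). None of these 3 families stood apart from random lists at 6 h or 24 h.

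Proteasome subunits fell in 40 of 46 cases with hairpin 2 (median -0.52, adjusted permutation p = 0.00050) and went both ways with hairpin 1 (8 up, 5 down; adjusted permutation p = 0.58). The CCT chaperonin fell in 8 of 9 subunits and rose in 1 with hairpin 2 (-1.14). Zinc finger (ZNF) genes rose in 98 of 327 cases and fell in 20 at 24 h (0.22), and with hairpin 1 they rose in 27 and fell in 58 of 368 (-0.12), both with an adjusted permutation p of 0.0020. RAB GTPase genes, which direct vesicle traffic, rose in 17 of 49 cases and fell in 6 with hairpin 1 (0.26). Kinesins fell in 14 of 28 and 16 of 29 cases with the hairpins and rose in 6 each time (-0.42 and -1.07). Nuclear-encoded complex I and cytochrome oxidase subunits did not stand apart from random lists in any comparison, with 12 rises and 0 falls among 46 with hairpin 1.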
